A study of Mus musculus with 22 samples.

How the data were processed

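RNA was sequenced from haematopoietic stem cells (HSCs) sorted from mice as lineage-negative, Kit-positive, Sca-1-positive cells (KSL) that lacked CD48 and carried CD150. The mice were Cd53 knockouts (KO) or wild-type littermates (WT), and received granulocyte colony-stimulating factor (G-CSF) for 7 days or saline. The 22 libraries form 6 groups by genotype, treatment and tissue: 4 WT and 3 KO libraries of bone marrow (BM) after saline, 3 WT and 4 KO libraries of BM after G-CSF, and 4 WT and 4 KO libraries of spleen after G-CSF. Spleens of saline-treated mice are not among the samples.

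The authors deposited 1 table of log2 values per library, beside log2 fold changes with bounds, signed linear fold changes, p-values and adjusted p-values of 4 comparisons. In each library the deposited log2 values step as log2 of a whole read number plus 0.5, in CPM (counts scaled to a common library total) of an effective library size that differs from the read total by a factor of 0.938 to 1.056. Every value of every library gave a whole read number within a tolerance of 0.05, so the read numbers could be recovered. The submitters' notes name bcl2fastq, STAR 2.5.1a, Subread featureCounts 1.4.6-p5, Salmon 0.8.2, edgeR and limma with the mouse build mm10, without saying which of these made the counts. The table has 13645 lines for 13594 distinct gene identifiers. The 51 repeated lines held identical values and were dropped. Symbols of 19 genes had been turned into dates and were looked up by identifier. Of the identifiers, 13588 were found in the mouse gene table, and positions are on build mm10 (GRCm38). A second worksheet, which repeats a few genes and holds unnamed values, was not used here.

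The recovered reads in the listed genes ran from 22578088 to 31268856 per library. One read was worth 0.0306 to 0.0465 CPM, and 3 reads, taken as the floor, were worth 0.092 to 0.139 CPM. The 10 most abundant genes took 5.02 to 5.8% of the reads, and the mitochondrial genes 0.44 to 0.71%. These depths cover counting error only.

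Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Genes above 1 CPM in at least 3 samples were tested, which kept 13571. The deposited log2 values went into a single limma model (R 4.3.3, limma 3.58.1, statmod 1.5.0) with a mean for each group, 16 residual degrees of freedom and a variance prior that follows expression. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and errors on log2 fold changes are standard errors (SE) from that model. There were 9 comparisons: KO against WT in 3 settings, G-CSF against saline in BM of each genotype, spleen against BM in each genotype, and the interactions of genotype with G-CSF and with tissue. Single values and list means per library were compared by two-sided exact permutation tests, using Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Figures were drawn with matplotlib 3.10.9.

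Each of 31 gene lists was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera asks whether the genes of a list rank higher or lower than the other genes. The test was repeated with a correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in 1 direction. The lists cover the DREAM and MuvB subunits, G2/M genes known as DREAM targets, G1/S genes, stem cell, progenitor and lineage markers, markers of other cell types, and stress, signalling and metabolic pathways. They were written from general knowledge and not derived from these samples. Where a list's members are counted past the threshold "adjusted over the list alone", the Benjamini-Hochberg step used only the genes of that list.

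The genes named are Cd53, up to 8 genes with the largest rise and up to 8 with the largest fall per comparison, the gate genes Kit, Ly6a (Sca-1), Cd48 and Slamf1 (CD150), and up to 4 genes of smallest p from each list that passed or that the study title concerns. The largest changes were taken among genes past the threshold with a mean of at least 3 log2 CPM in the higher group and no overlap between the groups, leaving out predicted genes, receptor segments and pseudogenes. Where no gene passed, the 3 genes of smallest p in each direction were taken. Some were left out for length, and some are not reported here. Genes named beside the module that follows Pdia3 and beside the authors' table, and values of Cd53 in KO libraries, were picked after their values were seen.

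The model was tested on simulated reads with the depths and spread of these libraries. Of genes changed 2-fold, 61.2 to 73.1% were recovered in the comparisons of KO with WT, 46.3% for the interaction of genotype with G-CSF and 50.7% for that with tissue. At 1.5-fold these shares were 29.9 to 34.3%, 11.9% and 13.4%. Between 2 and 11 unchanged genes were called per comparison. The simulated comparisons of KO with WT called 125 to 142 genes each, against 1, 20 and 2 genes in the real ones. With so few calls the Benjamini-Hochberg cutoff is stricter. The shares recovered can therefore be too high for the real comparisons of KO with WT. A planted list of 40 genes changed 1.3-fold was called in each of the 9 comparisons, and 0 of 20 unchanged lists were called. Each simulated gene was drawn independently of the others. The simulation therefore does not show how many false calls arise from correlation between genes or from variation shared within libraries.

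The settings varied by plan were no filter or a filter at 4 CPM, median-centred and quantile-normalised values, offsets of 0.25 and 4 CPM, sample weights, a model of the compared groups alone, variance priors without trend or robust to outliers, the replicate number as a block, and each library left out in turn. Added after the data were seen were voom on the recovered reads, voom with sample quality weights, scaling to the reads in the listed genes, removal of each library's trends with GC content and gene length, and leaving out both libraries that stood apart from their groups. Exact tests of list means per library, the tetraspanin list without Cd53, and the comparison of spleen after G-CSF with BM after saline were also added then. A covariate built from the residuals was tried after the data were seen and left out, since such a covariate leaves the folds as they are and lowers the spread.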

Results

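Gene expression was measured by RNA sequencing in HSCs of Cd53 KO mice and WT littermates, in BM after saline, in BM after 7 days of G-CSF, and in spleen after G-CSF. G-CSF is a cytokine that drives granulocyte production and moves stem cells out of the marrow, and Cd53 encodes a tetraspanin of leukocyte membranes. Groups held 3 or 4 libraries each, 22 in all, with 22578088 to 31268856 reads per library in the listed genes.

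The first comparison asks how far the knockout lowered Cd53 (ENSMUSG00000040747, chromosome 3, 106759921 to 106790149 on the minus strand, build mm10). Cd53 was lower in every KO library than in every WT library of the same setting. In saline BM it lay at 3.07 ± 0.91 log2 CPM (SD, n = 3) in KO and 5.92 ± 0.18 (n = 4) in WT, exact permutation p = 0.0571, which is the smallest that design allows. In BM after G-CSF it lay at 6.32 ± 0.22 (n = 4) and 9.73 ± 0.15 (n = 3), exact permutation p = 0.0571, again the smallest possible. In spleen it lay at 6.30 ± 0.10 and 9.63 ± 0.11 (n = 4 each), exact permutation p = 0.0286, the smallest possible there. KO libraries thus kept 13.9%, 9.4% and 9.9% of the WT level in these settings. The limma log2 fold changes were -2.84 ± 0.24, -3.41 ± 0.24 and -3.33 ± 0.22 (SE). Cd53 itself rose with G-CSF, by 3.82 ± 0.24 in WT and 3.25 ± 0.24 in KO BM.

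**Figure D1:**
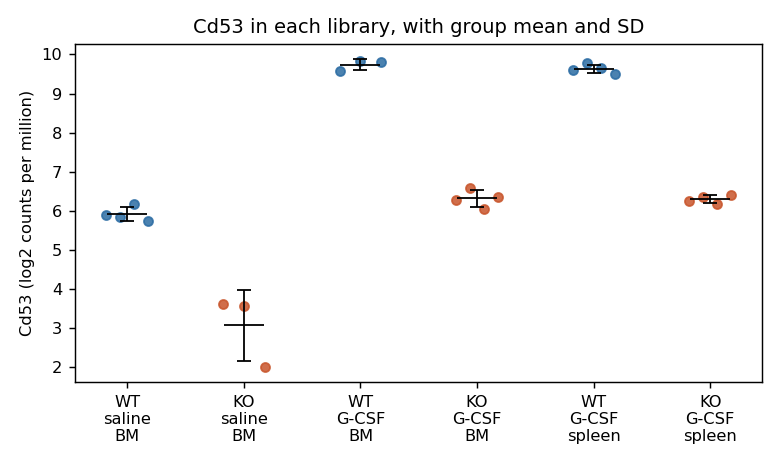
Cd53 in log2 CPM for each library (points; blue WT, orange KO) in the 6 groups, with the mean and SD (black). Each KO group lies below the WT group of its setting, and both genotypes lie higher after G-CSF than after saline.

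In unstressed marrow, KO and WT HSCs differed in Cd53 alone at the threshold. It was the 1 gene of 13571 past the threshold, and it was lower in KO. The gate genes had log2 fold changes of 0.32 ± 0.12 (Ly6a), 0.43 ± 0.18 (Slamf1), 0.18 ± 0.31 (Cd48) and 0.01 ± 0.20 (Kit), none past the threshold. Gata1, an erythroid transcription factor, had a log2 fold change of 0.95 ± 0.26 and Pes1, a ribosome assembly factor, one of 0.62 ± 0.17 (adjusted p = 0.853 for each). The G2/M genes that DREAM represses, among them the mitotic kinesins Kif14 (-0.62 ± 0.23) and Kif11 (-0.27 ± 0.17), ranked slightly lower in KO, with a median of -0.14 over 69 genes and 0 past the threshold (0 adjusted over the list alone). The camera test gave this list adjusted p = 0.00103 at the preset correlation and adjusted p = 0.610 with an estimated correlation, and the median became 0.01 without KO saline replicate 1. Immediate early genes, which respond within minutes to handling, had a median of -0.37 over 33 members, 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.222 with an estimated correlation). The 8 other lists past the preset test, erythroid, interferon, ribosome biogenesis, oxidative phosphorylation, cholesterol, mitochondrial, DNA repair and G1/S genes, had medians between -0.16 and 0.25, 0 genes past the threshold, at most 1 per list adjusted over the list alone, and adjusted p = 0.222 to 0.610 with an estimated correlation. Without KO saline replicate 1 the G1/S median was 0.04, and without KO saline replicate 3 the medians of oxidative phosphorylation and mitochondrial genes were 0.002 and -0.03. Of the 10 lists, the erythroid and immediate early genes kept their call without any single library, but their medians moved. The erythroid median of 0.25 became 0.07 without WT saline replicate 3 and 0.43 without WT saline replicate 1, and the immediate early median became -0.21 without KO saline replicate 1. The others lost it without WT saline replicate 1 or 2 or KO saline replicate 1 or 3, at adjusted p = 0.0526 to 0.915. By limma 510 genes had an unadjusted p under 0.05, where chance gives 679. Without KO saline replicate 2 the count was 6, all lower in KO, and it was 2 without WT saline replicate 2, WT saline replicate 4 or KO saline replicate 3.

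In marrow after G-CSF, 17 of 13571 genes were higher in KO HSCs than in WT HSCs and 3 were lower. Among the rises were Neil3, a DNA glycosylase of proliferating cells (1.47 ± 0.30), the helicase Pif1 (1.17 ± 0.24), the kinetochore kinesin Cenpe (1.03 ± 0.20), the mitotic gene Prr11 (1.03 ± 0.19) and Cit, a kinase of cytokinesis (0.88 ± 0.15). Oscp1 (1.23 ± 0.23), Socs2, a feedback inhibitor of cytokine signalling (0.91 ± 0.16), and Arhgef39 (0.80 ± 0.16) rose as well. Beside Cd53, the genes that fell were Dnajb9, a chaperone of the endoplasmic reticulum (-0.96 ± 0.20), and Vcam1, at a low level of 2.37 log2 CPM in WT and 0.13 in KO (-2.24 ± 0.46), which was named after its values were seen.

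The G2/M targets of DREAM ranked higher in KO in this comparison at the preset correlation. Their median log2 fold change was 0.60, 66 of 69 had a positive sign, and 2 rose past the threshold over all genes, Cenpe and Cdca2 (0.71 ± 0.13). Adjusted over the list alone, 48 rose and 0 fell. Kif22 (0.68 ± 0.15, adjusted p = 0.0554) and Kif14 (1.03 ± 0.23, adjusted p = 0.0663) lay just short of the threshold. Camera gave adjusted p = 2.28e-32 at the preset correlation, adjusted p = 0.297 with an estimated correlation, and fry adjusted p = 0.0407. Averaged per library, the 69 genes lay 0.55 log2 units higher in KO, and 4 of 4 KO libraries exceeded every WT library (exact permutation p = 0.0571, the smallest possible; adjusted p = 0.154 over 27 such tests). Genes of G1/S, which DREAM also represses with other complexes, had a median of 0.13 over 60 members, 0 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.738 with an estimated correlation). The 11 DREAM and MuvB subunits had a median of -0.13, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.445), with Rbl2 at -0.47 ± 0.19.

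The lists of the unfolded protein response and of ribosome biogenesis ranked lower in KO marrow after G-CSF at the preset correlation, with adjusted p = 0.248 and adjusted p = 0.327 with an estimated correlation. The first list had a median of -0.21 over 36 genes, with Dnajb9 past the threshold, 2 lower adjusted over the list alone, and Hspa5, the main chaperone of the endoplasmic reticulum, at -0.69 ± 0.18 (camera adjusted p = 7.26e-05). The second had a median of -0.19 over 40 genes, 0 past the threshold and 3 lower adjusted over the list alone, with Ddx21 at -0.41 ± 0.11 (camera adjusted p = 1.27e-05). Interferon genes had a median of 0.14 over 49 members, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00260; adjusted p = 0.660 with an estimated correlation). Without WT BM replicate 2 or KO BM replicate 2 the interferon list gave adjusted p = 0.190 and 0.159 and the G1/S list 0.0801 and 0.253; over the omissions their medians ran from 0.10 to 0.22 and from 0.09 to 0.19. The number of single genes past the threshold rested on individual libraries: it was 504 without KO BM replicate 3 (245 higher, 259 lower), 1 without KO BM replicate 2, 3 without KO BM replicate 1 and 7 without WT BM replicate 3. Without KO BM replicate 2, Neil3 was at adjusted p = 0.116 and Cenpe at 0.0848, and without KO BM replicate 3, Kif14 was at 0.0272, Hspa5 at 0.0457 and Rbl2 at 0.0359. It was 8 with sample weights, 11 with voom, 3 with the compared groups alone and 1 with no variance trend. In these last 2 settings, which leave the folds as they are, and without KO BM replicate 2, 0 genes passed as higher in KO. Without that library the folds stayed close to their size, as for Neil3 (1.47), Pif1 (1.17) and Cenpe (1.04). The 10 genes past the threshold that are named here beside Cd53 and Vcam1 each lost their call in 3 to 6 of 7 omissions of 1 library, at adjusted p = 0.054 to 0.23.

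In spleen, where HSCs collect after mobilisation, the G2/M targets again ranked higher in KO at the preset correlation, with 0 of 69 past the threshold and adjusted p = 0.150 with an estimated correlation. Past the threshold were Cd53 and Phactr2, a regulator of phosphatase and actin, which fell by 1.77 on the log2 scale (SE 0.28, adjusted p = 0.0161). The median of the G2/M targets was 0.58, and 67 of 69 had a positive sign. Adjusted over the list alone, 51 rose and 1 fell. Top2a, the topoisomerase of mitotic chromosomes, was at 0.73 ± 0.15, the kinesin Kif11 at 0.76 ± 0.16 and the separase Espl1 at 1.09 ± 0.24 (adjusted p = 0.117 for each). Camera gave the list adjusted p = 7.08e-39 at the preset correlation, and fry adjusted p = 0.0319. The list mean was 0.56 higher in KO, with 4 of 4 KO libraries above every WT library (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.154 over 27 tests). WT spleen replicates 1 and 2 had list means of -0.72 and -0.77, and replicates 3 and 4 of -0.10 and -0.21. The lowest KO spleen library lay at -0.063, close to the -0.104 of WT replicate 3.

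G1/S genes had a median of 0.33 in KO spleen, 0 of 60 past the threshold and 10 higher adjusted over the list alone, with the polymerase subunit Pold1 at 0.99 ± 0.22 (camera adjusted p = 1.48e-13; adjusted p = 0.465 with an estimated correlation). Genes of homologous recombination and the Fanconi pathway had a median of 0.25 over 35 members, 0 past the threshold and 3 higher adjusted over the list alone, with the helicase Blm at 0.58 ± 0.15 (camera adjusted p = 5.66e-06; adjusted p = 0.150 with an estimated correlation). Oxidative phosphorylation had a median of -0.21 over 70 genes, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 7.30e-13; adjusted p = 0.465 with an estimated correlation). Of 24 tetraspanins, Cd53, the targeted gene, alone fell. Without it the other 23 had a median of -0.10, 0 past the threshold and 2 lower adjusted over the list alone, Cd37 (-0.34 ± 0.10) and Cd63 (-0.34 ± 0.10), and the list did not pass (camera adjusted p = 0.122; adjusted p = 0.392 with an estimated correlation). The DREAM and MuvB subunits had a median of 0.06, 0 past the threshold, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.551). By limma 1598 genes had an unadjusted p under 0.05. With sample weights 207 genes were higher and 102 lower, and with voom and quality weights 169 and 107. The count was 31 without WT spleen replicate 3, and it was 1 without WT spleen replicate 2 or 4 or KO spleen replicate 2, 3 or 4, with the compared groups alone, or with no variance trend. In those 5 omissions Phactr2 was at adjusted p = 0.0626 to 0.150, and without WT spleen replicate 3 Top2a was at 0.00634, Espl1 at 0.0143 and Kif11 at 0.0156.

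**Figure D2:**
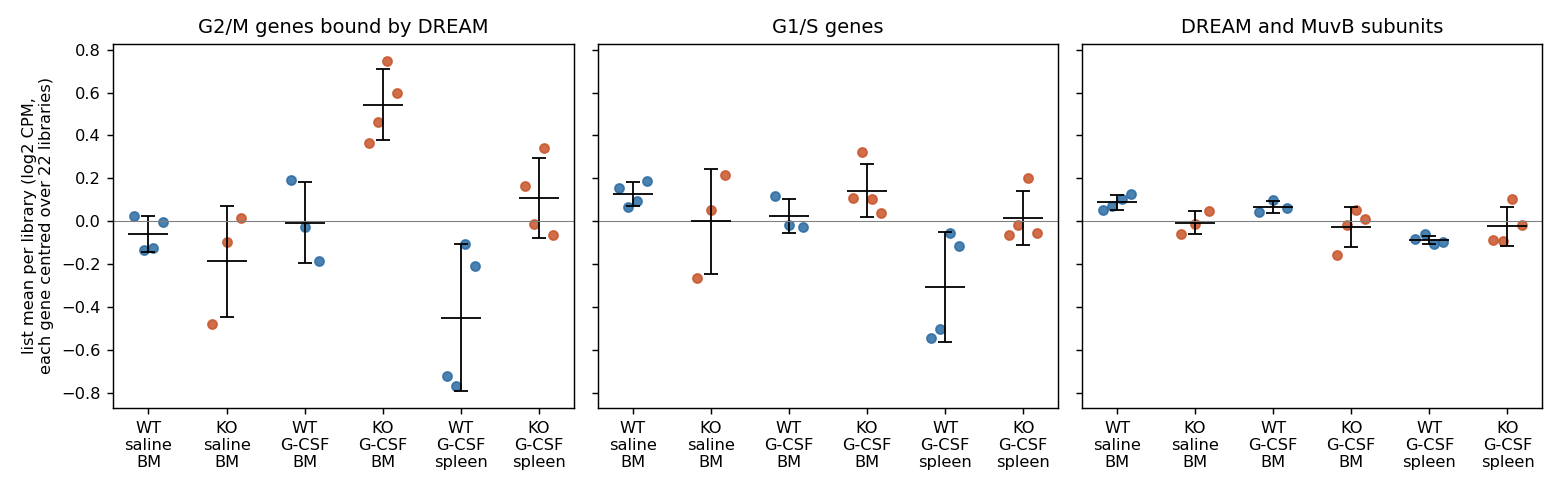
Mean per library of 69 G2/M genes known as DREAM targets, 60 G1/S genes and 11 DREAM and MuvB subunits, in log2 CPM with each gene centred over the 22 libraries (points; blue WT, orange KO; black, mean and SD of the group). After G-CSF each KO library lies above each WT library of its tissue in the left panel.

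The response of WT marrow HSCs to G-CSF was broad, with 764 genes higher and 764 lower. Among the largest rises were Wfdc17 (5.63 ± 0.24), the mucin Muc1 (5.54 ± 0.23), Tmem215 (6.34 ± 0.42), Dntt, the terminal transferase of early lymphoid progenitors (5.42 ± 0.58), and the complement gene C4b (5.25 ± 0.51). Among the largest falls were Cyp26b1, which breaks down retinoic acid (-3.77 ± 0.82), Plk2 (-3.69 ± 0.41), the stem cell receptor Neo1 (-3.34 ± 0.39), Runx1t1 (-3.27 ± 0.35), Ehd2 (-2.64 ± 0.44), Igf1 (-2.64 ± 0.27) and Inhba (-2.58 ± 0.81), whose call was lost in 6 of 7 omissions of 1 library (adjusted p = 0.0536 to 0.225). The gate genes Cd48 (1.78 ± 0.31) and Ly6a (1.16 ± 0.12) rose, and Kit (-0.47 ± 0.20) and Slamf1 (-0.20 ± 0.18) did not pass.

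Some stem cell genes fell and some progenitor genes rose with G-CSF in WT marrow. Of 49 HSC identity genes 17 fell, including the cell cycle inhibitor Cdkn1c (-1.62 ± 0.22), and 2 rose, Ifitm1 (0.91 ± 0.09) and Ly6a. With p adjusted over the list alone, 23 fell and 3 rose (camera adjusted p = 1.02e-07; adjusted p = 0.00102 with an estimated correlation). Of 31 quiescence genes 8 fell, including Egr1 (-2.15 ± 0.42), and 1 rose. Adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 0.00612; adjusted p = 0.0505 with an estimated correlation). Of 17 multipotent progenitor genes 9 rose, including Plac8 (2.32 ± 0.19), Cd34 (1.09 ± 0.13) and Adgrl4 (1.06 ± 0.14), and 0 fell. In all, 10 rose adjusted over the list alone (camera adjusted p = 2.20e-08; adjusted p = 0.0196 with an estimated correlation). Of 15 genes of granulocyte progenitors 5 rose, among them the protease Prtn3 (1.37 ± 0.16) and the G-CSF receptor Csf3r (1.09 ± 0.20), with 6 adjusted over the list alone (camera adjusted p = 0.00445; adjusted p = 0.0659 with an estimated correlation).

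Some cytokine, secretory and growth genes rose in the same comparison. Of 26 STAT3 and STAT5 response genes 9 rose, among them the feedback inhibitor Socs3 (5.23 ± 0.24), Gadd45g (3.51 ± 0.39) and Il4ra (1.39 ± 0.14), and 2 fell, including Ccnd2 (-0.89 ± 0.12). Adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 3.14e-06; adjusted p = 0.0505 with an estimated correlation). Of 36 genes of the unfolded protein response 11 rose, among them Vldlr (4.61 ± 0.13), the transcription factor Xbp1 (1.17 ± 0.19) and Hspa5 (1.02 ± 0.18). Adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 4.90e-08; adjusted p = 0.0163 with an estimated correlation). Of 40 genes of ribosome biogenesis 10 rose, including Ddx21 (0.53 ± 0.11), with 11 adjusted over the list alone (camera adjusted p = 1.91e-07; adjusted p = 0.0659 with an estimated correlation). Of 31 adhesion genes 7 rose and 2 fell, including Cd93 (-0.81 ± 0.11). Adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.0499; adjusted p = 0.122 with an estimated correlation). This call was lost without WT saline replicate 2, 3 or 4 or WT BM replicate 1 or 3, at adjusted p = 0.0503 to 0.110. For the G2/M targets the median was 0.08, with Bub1 (0.55 ± 0.18) higher and Kif23 (-0.88 ± 0.21) lower over all genes, and 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.415). The list median ran from -0.01 without WT BM replicate 1 (adjusted p = 0.650) to 0.195 without WT BM replicate 3 (adjusted p = 0.0215). The call of Bub1 was lost in 5 of 7 omissions of 1 library (adjusted p = 0.0932 to 0.271) and that of Kif23 without WT BM replicate 3 (adjusted p = 0.0602). G1/S genes had a median of -0.07, with 4 lower, including E2f1 (-0.94 ± 0.20), and 3 lower adjusted over the list alone (camera adjusted p = 0.133, and 0.0285 without WT BM replicate 1). Oxidative phosphorylation had a median of 0.13 and 0 of 70 genes past the threshold, with 0 adjusted over the list alone (camera adjusted p = 0.00204; adjusted p = 0.685 with an estimated correlation). Of 25 cholesterol genes 5 rose, with 8 adjusted over the list alone (camera adjusted p = 0.000274; adjusted p = 0.374 with an estimated correlation), and of 9 T and NK cell genes 3 rose, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00931; adjusted p = 0.0505 with an estimated correlation). The split into higher and lower moved to 556 and 1047 when reads were scaled to the listed genes, and to 1115 and 593 with GC and length trends removed. Without WT BM replicate 3 the count of genes was 967.

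KO marrow HSCs responded to G-CSF with 757 genes higher and 585 lower. The largest changes included Dntt (6.81 ± 0.58), Tmem215 (6.79 ± 0.42), Wfdc17 (5.18 ± 0.24), Muc1 (5.10 ± 0.23), Socs3 (4.23 ± 0.24) and P-selectin, Selp (4.17 ± 0.36), which rose, and Inhba (-4.48 ± 0.81), Plk2 (-3.56 ± 0.41), Ehd2 (-3.34 ± 0.44) and the adhesion molecule Vcam1 (-3.10 ± 0.46), which fell. The fall of Inhba was enlarged by KO BM replicate 2, at -4.02 log2 CPM, under the floor of 3 reads. The other KO BM libraries after G-CSF lay at 0.19 to 0.72. The response correlated with that of WT across genes, with Pearson r of 0.619 and Spearman rho of 0.498 over 13571 genes, which are not independent replicates. Of the genes called, 417 were higher in both genotypes, where 42.6 would be shared by chance, 280 were lower in both against 32.9, and 0 went opposite ways.

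Of the G2/M targets of DREAM, 44 of 69 rose with G-CSF in KO marrow and 0 fell, with a median of 0.76, and 57 rose adjusted over the list alone. Among them were the mitotic kinesin Kif20a (1.18 ± 0.17), the spindle factor Tpx2 (1.14 ± 0.17) and Prc1, which builds the midzone of the spindle (1.01 ± 0.15). Camera gave adjusted p = 1.21e-27 at the preset correlation and adjusted p = 0.215 with an estimated correlation, and fry gave adjusted p = 0.00267. Of the 11 DREAM and MuvB subunits Rbl2, the pocket protein p130, fell (-0.61 ± 0.19, adjusted p = 0.0403, lost in 6 of 7 omissions of 1 library at adjusted p = 0.0801 to 0.141), with 1 lower adjusted over the list alone and a list median of 0.07 (camera adjusted p = 0.983). G1/S genes had a median of 0.12, with 0 of 60 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0637, and 0.000271 to 0.0458 without KO saline replicate 2 or 3 or KO BM replicate 1, 3 or 4). Their median ran from 0.001 without KO saline replicate 1 (adjusted p = 0.988) to 0.23 without KO saline replicate 3.

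Stem cell and progenitor lists moved in KO marrow as well. Of the HSC identity genes 18 fell, among them Angpt1 (-1.33 ± 0.16) and Eya2 (-1.10 ± 0.14), and 3 rose; adjusted over the list alone 23 fell and 3 rose (camera adjusted p = 1.47e-09; adjusted p = 0.000284 with an estimated correlation). Of the multipotent progenitor genes 11 rose, with 12 adjusted over the list alone (camera adjusted p = 1.48e-11; adjusted p = 0.00859 with an estimated correlation). Of the STAT3 and STAT5 genes 11 rose and 1 fell, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.000297; adjusted p = 0.215 with an estimated correlation). Of 15 genes of late neutrophil granules and maturation 5 rose, including the integrin Itgam (2.24 ± 0.22), and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0284; adjusted p = 0.215 with an estimated correlation). Of 30 megakaryocyte and platelet genes 10 fell, including Pf4 (-2.17 ± 0.31), and 2 rose, including Selp; adjusted over the list alone 12 fell and 3 rose (camera adjusted p = 0.0368; adjusted p = 0.215 with an estimated correlation). The granule list gave adjusted p = 0.103 without KO BM replicate 4, where its median went from 1.79 to 0.995. The megakaryocyte list gave 0.0553 without KO BM replicate 1 and 0.1 without KO saline replicate 3, and its median of -0.29 became -0.05 without KO saline replicate 2. The count of all genes was 865 without KO saline replicate 1 and 613 with the compared groups alone. Its split was 589 higher and 799 lower when reads were scaled to the listed genes, and the count was 2076 without both libraries that stood apart.

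Whether the response to G-CSF differed between genotypes was tested by the interaction. By limma 0 of 13571 genes passed, and 970 had an unadjusted p under 0.05. Among the smallest p-values were those of Cit (1.15 ± 0.21), Kif14 (1.65 ± 0.32) and Pif1 (1.57 ± 0.34) among positive values and Pes1 (-1.11 ± 0.24) among negative ones (adjusted p = 0.243 to 0.259). Across the G2/M targets the median interaction was 0.68, with 68 of 69 positive, 0 past the threshold and 34 adjusted over the list alone (camera adjusted p = 7.82e-35; adjusted p = 0.122 with an estimated correlation; fry adjusted p = 0.0675). The list mean rose with G-CSF by 0.68 more in KO than in WT (exact permutation p = 0.0122 over 1225 arrangements, adjusted p = 0.154 over 27 tests). These arrangements, like those for the interaction with tissue below, redraw genotype within each treatment or tissue. They test the absence of any genotype effect, not of the interaction alone. The count of single genes was 7 without KO saline replicate 2, 3 without KO saline replicate 3, and 1 without WT saline replicate 2 or WT BM replicate 2.

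Spleen and marrow HSCs of G-CSF-treated WT mice differed in 940 genes higher and 927 lower in spleen. Among the largest rises were those of Tm4sf1 (3.50 ± 0.66), Neo1 (3.43 ± 0.39), Ehd2 (2.70 ± 0.44), Phactr2 (2.59 ± 0.31), the Notch ligand Jag1 (2.49 ± 0.26), the lamin gene Lmna (2.41 ± 0.24) and Xdh (2.09 ± 0.17). Among the largest falls were those of Apoe (-2.88 ± 0.66), the disulfide isomerase Pdia3 (-2.80 ± 0.62), Sdf2l1 (-2.76 ± 0.64) and the actin-binding profilin Pfn1 (-2.60 ± 0.66), 4 genes that also differed strongly between libraries of the same group. Without WT BM replicate 1 Apoe was at adjusted p = 0.0631 and Pfn1 at 0.0732. In the groups compared, Pfn1 spanned 8.78 to 9.59 log2 CPM in WT marrow and 5.92 to 7.48 in WT spleen. Among the 4 KO marrow libraries after G-CSF, which are outside this comparison, it spanned 6.31 to 9.73. Of 112 genes that followed Pdia3 in this way, 57.1% were lower in WT spleen, against 6.8% of all genes.

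The interferon list ranked higher and the G2/M and G1/S lists ranked lower in WT spleen than in WT marrow at the preset correlation. With an estimated correlation these calls were not kept. Of 49 interferon genes 27 rose, among them Xaf1 (0.83 ± 0.12), Rtp4 (0.98 ± 0.14), Gbp3 (0.80 ± 0.12) and the RNA sensor Dhx58 (1.08 ± 0.17), and 0 fell. In all, 35 rose adjusted over the list alone (camera adjusted p = 2.09e-18; adjusted p = 0.197 with an estimated correlation). Of the 69 G2/M targets 14 fell, including Plk4 (-1.46 ± 0.27) and Racgap1 (-1.16 ± 0.24), and 1 rose. With p adjusted over the list alone, 27 fell and 1 rose (camera adjusted p = 1.97e-10; adjusted p = 0.469 with an estimated correlation). Of the G1/S genes 11 fell, with 14 adjusted over the list alone (camera adjusted p = 5.12e-05; adjusted p = 0.541 with an estimated correlation); 4 of the 60 follow Pdia3. Of the HSC identity genes 15 rose, including Procr (0.54 ± 0.11), and 3 fell; adjusted over the list alone 17 rose and 5 fell (camera adjusted p = 0.0299, and 0.113 without WT BM replicate 2; adjusted p = 0.197 with an estimated correlation). Of the DREAM and MuvB subunits 2 fell, Lin54 (-0.62 ± 0.18) and Rbl2 (-0.62 ± 0.19), with 2 lower adjusted over the list alone (camera adjusted p = 0.240). Each of these calls was lost in 5 of 7 omissions of 1 library (adjusted p = 0.0513 to 0.116 for Lin54, 0.0505 to 0.144 for Rbl2). Myc fell by 1.10 on the log2 scale (SE 0.16).

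Lists of secretory, growth and cytokine genes ranked lower in WT spleen than in WT marrow at the preset correlation. Of the genes of the unfolded protein response 9 fell, including Vldlr (-1.43 ± 0.13), with 10 adjusted over the list alone (camera adjusted p = 2.81e-05, and 0.188 with an estimated correlation). Of the 36 genes on that list, 2 belong to the set that follows Pdia3. Of the genes of ribosome biogenesis 10 fell, with 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.469 with an estimated correlation). Of the STAT3 and STAT5 genes 4 fell and 1 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.397 with an estimated correlation). Erythroid genes (4 of 13 lower, including Gata1 at -1.27 ± 0.26), DNA repair genes (3 of 35 lower) and cholesterol genes (4 of 25 lower) ranked lower and the 7 mitochondrial genes (2 higher) ranked higher, with 5, 2, 4 and 3 adjusted over the list alone in those directions and adjusted p = 0.339 to 0.553 with an estimated correlation. The erythroid and mitochondrial calls were each lost in 4 of 7 omissions of 1 library (adjusted p = 0.0569 to 0.145) and the cholesterol call in 2 (adjusted p = 0.0535 and 0.0595). With median-centred libraries, which moved the median of all genes by 0.11, 1628 genes were higher and 609 lower, with GC and length trends removed 625 and 1073, and with sample weights 2863 in all. The count was 674 and 978 without WT BM replicates 1 and 3, and 1078 and 1058 without WT spleen replicates 1 and 2.

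KO spleen HSCs differed from KO marrow HSCs in 129 genes higher and 43 lower. Ehd2 (3.44 ± 0.40), Neo1 (2.73 ± 0.36), Lmna (2.63 ± 0.22), Jag1 (2.32 ± 0.24) and Ahnak (2.23 ± 0.27) rose, and Chad (-1.64 ± 0.21), the iron exporter Slc40a1 (-1.35 ± 0.24) and Vldlr (-1.34 ± 0.12) fell. Of the interferon genes 16 rose, including Irf7 (1.01 ± 0.19), Mx1 (2.07 ± 0.45) and Oas1a (0.62 ± 0.12), with 36 adjusted over the list alone (camera adjusted p = 2.37e-34; adjusted p = 0.0267 with an estimated correlation). Of the HSC identity genes 7 rose and 0 fell, with 12 and 1 adjusted over the list alone (camera adjusted p = 5.33e-06; adjusted p = 0.00413 with an estimated correlation). Of the multipotent progenitor genes 3 fell, including Cd34 (-0.86 ± 0.12) and Flt3 (-1.26 ± 0.30); adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 8.44e-06; adjusted p = 0.101 with an estimated correlation). The G2/M targets had a median of -0.41, with 68 of 69 negative, 1 lower past the threshold (Tpx2, -0.62 ± 0.16, lost in 7 of 8 omissions of 1 library at adjusted p = 0.0711 to 0.189) and 31 adjusted over the list alone (camera adjusted p = 1.09e-26; adjusted p = 0.198 with an estimated correlation). The 7 other lists past the preset test, G1/S, B cell, STAT, immediate early, unfolded protein, DNA repair and oxidative phosphorylation genes, had at most 2 genes past the threshold, at most 4 adjusted over the list alone, medians between -0.24 and 0.25 and adjusted p = 0.198 to 0.736 with an estimated correlation. Leaving out 1 of the 8 libraries ended the calls of oxidative phosphorylation (4 omissions, adjusted p = 0.0688 to 0.886, with a median of 0.002 without KO spleen replicate 4), STAT genes (3, adjusted p = 0.0688 to 0.517, with a median of -0.01 without KO BM replicate 3) and B cell genes (3, adjusted p = 0.0798 to 0.192). Without KO BM replicate 2 the calls of G1/S genes (median -0.06, adjusted p = 0.229) and DNA repair genes (adjusted p = 0.0707) were also lost. Flt3 lost its call in 6 of 8 omissions (adjusted p = 0.0554 to 0.149) and Mx1 in 3 (adjusted p = 0.0525 to 0.0904). The count of genes was 110, 99, 97 and 101 without KO spleen replicates 1 to 4 in turn, 78 with the compared groups alone, 110 with no variance trend and 102 without both libraries that stood apart. Its split was 104 higher and 67 lower with GC and length trends removed.

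The interaction of genotype with tissue called 0 of 13571 genes by limma, with 1758 at an unadjusted p under 0.05. Phactr2 (-2.12 ± 0.42) was among those of smallest p (adjusted p = 0.177). The G2/M targets had a median of -0.02 (camera adjusted p = 0.862), which ran from -0.17 without WT spleen replicate 1 to 0.10 without WT spleen replicate 3, with 0 past the threshold and 0 adjusted over the list alone, and the list mean differed by 0.01 (exact permutation p = 0.985 over 2450 arrangements). The count of genes was 245 without KO BM replicate 3, 22 without both libraries that stood apart, 2 without WT BM replicate 2, and 1 without WT BM replicate 1 or WT spleen replicate 3.

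**Figure D3:**
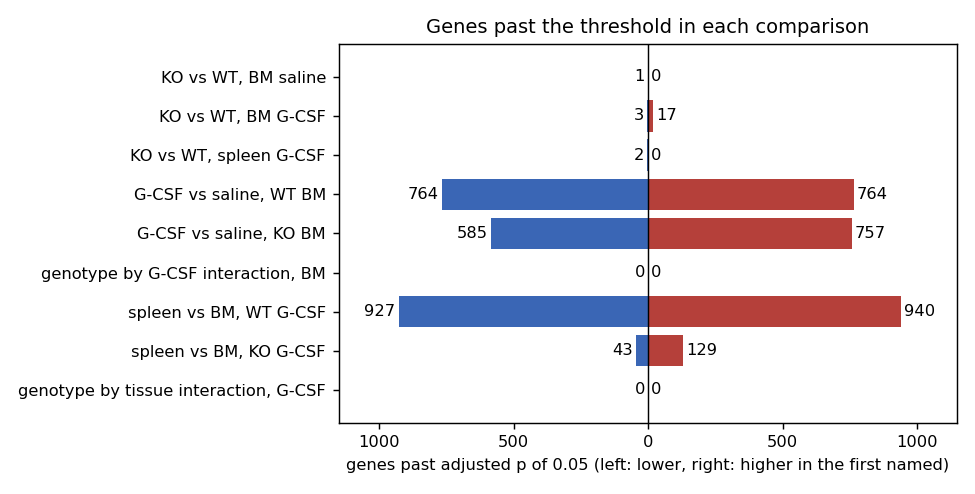
Number of genes past an adjusted p of 0.05 in each of the 9 comparisons, with those higher in the first-named group to the right (red) and those lower to the left (blue). The comparisons of KO with WT call 1, 20 and 2 genes.

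**Figure D4:**
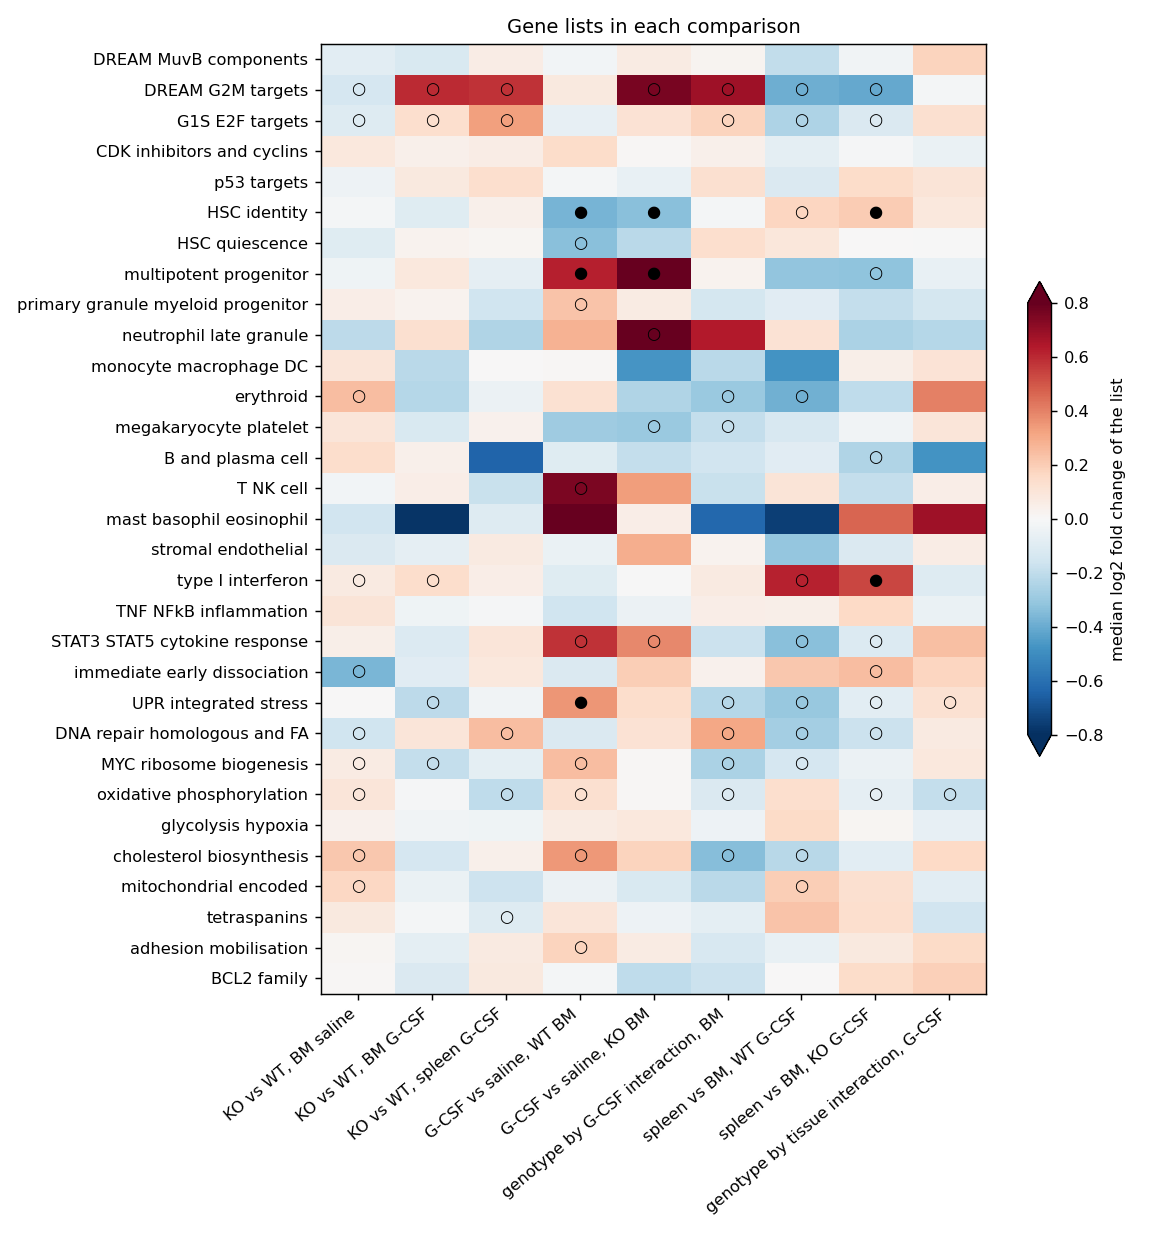
Median log2 fold change of each of the 31 gene lists (lines) in each comparison (columns), on a colour scale from -0.8 to 0.8. Open circles mark lists past an adjusted p of 0.05 in the camera test with a preset correlation (70 of 279), filled circles those that also pass with an estimated correlation (7).

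Across genes, the log2 fold changes of KO against WT correlated little between settings. Pearson r of the log2 fold changes was 0.036 between saline BM and BM after G-CSF (Spearman 0.055), 0.018 between saline BM and spleen (-0.116), and -0.012 between BM and spleen after G-CSF (-0.052). Genes are not independent replicates. With 1, 20 and 2 genes past the threshold, low correlations can come from noise and do not show that the effect differs between settings. The list mean of the G2/M targets differed by 0.55 in BM and 0.56 in spleen after G-CSF, and by -0.13 in saline BM.

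The authors' deposited table holds 4 comparisons. It lists 302 genes at an adjusted p under 0.05 between KO and WT spleen, 190 higher and 112 lower, and 1 gene between the genotypes in saline BM. Among the G2/M targets of DREAM it lists 38 as higher and 1 as lower in KO spleen, among them Top2a at 0.85 on the log2 scale; outside that list it gives Neil3 at 1.15. Its log2 fold changes correlated with those computed here at Pearson r of 0.927 for spleen and 0.948 for saline BM, across genes. Between spleen after G-CSF and BM after saline it lists 4708 genes in WT and 1191 in KO. The same contrasts, computed here after that table was seen, gave 2866 and 853, and 4683 and 1183 with sample weights. For KO against WT spleen, the main model here called 2 genes, both also called in the authors' table. With sample weights it called 309, of which 207 were higher and 102 lower.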

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

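The tests of the G2/M list against GC content, single libraries, progenitor markers and genotype were chosen after the results were seen. So were those of Cd53 against a pool of all libraries and against WT cells, the exact tests of list means and the splits for the correlation between genotypes. For the splits for counts of genes, the Pdia3 tests and the test of reads carried over, predictions were written before the outcomes. The patterns behind the Pdia3 tests and the test of reads carried over were themselves first seen in these data. In groups of 4 libraries, a library far from the other 3 was looked for in 99 values. These were genes named here, the means of the DREAM subunit, G2/M and G1/S lists, the reads in listed genes and the mitochondrial share. Such a gap was found in 25 of 396 groups, where chance gives about 1 in 20, or 20.

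In WT saline BM, replicate 1 lay above the others in Top2a (8.79 log2 CPM, others 8.56 to 8.59), Tpx2 (6.65, others 6.35 to 6.37), Bub1 (5.49) and Kif20a (6.49), 4 genes of mitosis, and below them in Pfn1 (6.52, others 9.04 to 9.54). In the same group replicate 3 was low in Tm4sf1 (-0.42), and replicate 4 in Arhgef39 (5.67) and Rtp4 (7.26). In KO BM after G-CSF, replicate 1 was low in Cd63 (8.11) and Tmem215 (5.16) and high in Tpx2 (7.44). Replicate 2 was low in Ly6a (7.98), Inhba (-4.02) and Ahnak (2.89) and high in Selp (7.94), replicate 3 was low in Cd48 (3.71), and replicate 4 was low in Pdia3 (6.88, others 9.35 to 9.66). In WT spleen, replicate 2 was low in Pif1 (2.54), Ccnd2 (9.02) and Irf7 (7.5) and high in Igf1 (3.77) and in the immediate early gene Fos (6.12, others 4.46 to 4.71), and replicate 4 was low in Ehd2 (2.98). In KO spleen, replicate 1 was low in Cd48 (3.73) and Pold1 (6.33).

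For 9 lists the response to G-CSF differed between genotypes in the camera test of the interaction at the preset correlation, and 0 of these calls held with an estimated correlation. Positive medians, higher in KO, were those of the G2/M targets (0.677; adjusted p = 7.82e-35, and 0.122 with an estimated correlation), DNA repair (0.309; 0.000101 and 0.184) and G1/S genes (0.176; 7.18e-06 and 0.501). Negative medians were those of cholesterol synthesis (-0.341; 0.000421 and 0.455), erythroid genes (-0.296; 0.00259 and 0.103), ribosome biogenesis (-0.251; 1.43e-08 and 0.103), the unfolded protein response (-0.228; 7.18e-06 and 0.103), megakaryocyte genes (-0.191; 0.0431 and 0.271) and oxidative phosphorylation (-0.116; 0.000421 and 0.542). The difference between spleen and BM varied with genotype for the unfolded protein response (0.120; 0.0445 and 0.791) and oxidative phosphorylation (-0.191; 0.00357 and 0.791). Without KO saline replicate 1 the G1/S call was lost (median 0.058, adjusted p = 0.0826), and without KO saline replicate 3 that of oxidative phosphorylation in the G-CSF interaction (median -0.025, adjusted p = 0.371). The cholesterol and erythroid calls were kept in each omission, but their medians became -0.182 without WT saline replicate 1 and -0.539 without KO saline replicate 1. The megakaryocyte call was lost when any 1 of 7 libraries was left out, namely WT saline replicate 3, WT BM replicates 1 and 3, KO saline replicates 2 and 3 and KO BM replicates 1 and 4 (adjusted p = 0.0581 to 0.178). Both tissue calls were lost without WT BM replicate 1, KO BM replicate 3, WT spleen replicate 4 or KO spleen replicate 4, that of the unfolded protein response also without 5 further libraries, WT BM replicate 3, KO BM replicate 4, WT spleen replicate 2 and KO spleen replicates 1 and 3 (adjusted p = 0.0595 to 0.199 in all).

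Other splits of the same libraries into groups of the same sizes were run through the same limma model. For G-CSF in WT BM, 1 of 35 splits, the real one, called as many genes as the real 1528 (highest other 357). For spleen against BM it was 1 of 35 in WT (1867, highest other 585) and 1 of 35 in KO (172, highest other 3). Chance is argued against for these 3 counts, but 1 of 35 is the lowest share possible and was not adjusted over comparisons. It cannot be excluded for the count of G-CSF in KO BM, where 2 of 35 splits called as many (1342, highest other 1451), nor for KO against WT, where 8 of 35 did in saline BM (1, highest other 2), 4 of 35 in BM after G-CSF (20, highest other 950) and 2 of 35 in spleen (2, highest other 3). For the agreement of the KO response to G-CSF with that of WT, which shares no libraries with it, the splits gave the same lowest share. Of 35 splits of the KO libraries 1, the real one, correlated as highly with the WT response across genes (Pearson r 0.619, highest other 0.431). For the interactions the real count was 0, so that 100 of 100 splits reached it (highest other 602 for G-CSF and 575 for tissue). Splits that call many times the real number point to a structure among the libraries of a group. KO BM replicate 3 had the lowest sample weight, 0.416.

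The G2/M targets of DREAM had medians of 0.60 in BM and 0.58 in spleen in KO against WT after G-CSF, with 2 and 0 of 69 past the threshold, adjusted p = 0.297 and 0.150 with an estimated correlation, and adjusted p = 0.154 for each exact test of list means. Bias from GC content or gene length is argued against as the whole cause, since removing these trends left medians of 0.554 and 0.539. A single library is argued against as well, since the lowest medians with 1 library left out were 0.490 and 0.441. Such omissions cannot show the part of 2 libraries together. In spleen, WT replicates 1 and 2 had list means of -0.720 and -0.766, and WT replicates 3 and 4 of -0.104 and -0.207. The KO spleen libraries ran from -0.063 to 0.344. Part of the spleen difference thus rests on WT replicates 1 and 2. Cycling multipotent, granulocyte or erythroid progenitors stay open. The highest marker list median was 0.086 in BM (multipotent progenitors, upper quartile 0.192) and -0.044 in spleen (erythroid, upper quartile 0.452). The highest WT level of the 3 lists was that of the erythroid genes in both tissues. It was 5.08 and 4.31 log2 CPM, below the 5.64 and 5.16 of the G2/M genes. Single markers lay far higher in WT BM after G-CSF, with Cd34 at 9.96 and Car2 at 12.02 log2 CPM. A small share of progenitors need not raise such markers, so the list medians cannot decide. Megakaryocyte and lymphoid progenitors were not part of this test. Whether genotype changes the response to G-CSF stays open, with an exact permutation p = 0.0122 that is 0.154 after adjustment. That p tests the absence of any genotype effect in BM, not of the interaction alone. The adjusted value of 0.154 is shared by each of the 27 tests with an exact permutation p of 0.0571 or less. Groups of 3 and 4 libraries cannot give a p below 0.0571, so this value partly reflects group size. A larger share of KO HSCs in G2 or M is a hypothesis that may account for the pattern and was not tested, since the proportion of cycling cells, which would decide it, was not measured here.

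A set of 112 genes, Pdia3 and those whose deviations from the group mean followed it at r of at least 0.8, varied widely between libraries of the same group. Bias from GC content or gene length is argued against, since removing these trends took the median SD within groups from 0.426 to 0.424. Depth stays open, since the mean of the set followed the log2 reads of the 22 libraries, both as deviations from the group means, at Pearson r of 0.22 (95% interval -0.3 to 0.63, permutation p = 0.334; Spearman 0.18, permutation p = 0.414), and at 0.13 without the 2 libraries farthest from the median depth. The Pearson r lay within the bound that the prediction had set for depth not being the cause. The upper end of its interval lay beyond that bound. Depth was therefore left open by the interval, a rule other than the one predicted. Of the 112 genes 64 were lower in WT spleen than in WT BM and 0 higher, so their part in that comparison cannot be told apart from this variation between libraries. No biological explanation was tested.

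Reads of Cd53 in KO libraries made up 9.4% of the WT level in BM after G-CSF. Carry-over from a pool of all libraries is argued against, since Cd53 in KO BM was 3.25 ± 0.54 (SE from the spread within these 2 groups alone, not from limma) log2 units higher after G-CSF than after saline. Carry-over between single libraries stays open: 8 of 9001 genes lay in KO saline BM below 0.5 times that share of their WT level after G-CSF, where 10 had been set as the bound. That test sets saline against G-CSF libraries, so it cannot decide on carry-over within a treatment. Cd53 itself lay at 4.0 to 12.2 CPM in KO saline BM, against 758.5 to 912.0 CPM in WT BM after G-CSF. WT cells in the KO libraries stay open as well, since 0 other genes were lower in KO in all 3 settings and none could serve as a measure. Transcripts left by the targeted allele are a biological explanation that may apply and was not tested.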

How the results depend on the processing

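The settings voom, voom with quality weights, scaling to listed reads, removal of GC and length trends and leaving out both libraries that stood apart (KO BM replicate 3 and KO spleen replicate 2) were chosen after seeing the data. Of 11245 values of named genes under other settings, 10727 kept their direction and side of the threshold, 140 passed it newly, 336 no longer passed, 42 moved and 0 reversed. Of 1352 list values, 1086 kept theirs, 19 passed newly, 202 no longer passed, 39 moved and 6 reversed. The cause of the changes was not tested unless given.

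The 20 genes of KO against WT in BM after G-CSF became 8 with sample weights, 3 with the compared groups alone (fewer libraries for the spread), 1 without a variance trend, 11 with voom, and 592 without both libraries that stood apart. The 2 genes in spleen became 309 with sample weights, 276 with voom and quality weights, and 1 with the compared groups alone or without a trend. G-CSF in KO BM gave 613 with the compared groups alone and 2076 without both libraries. Spleen against BM gave 2863 in WT with sample weights, and in KO 78 with the compared groups alone, 110 without a trend and 102 without both libraries. The interaction with tissue gave 22 without both libraries.

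Leaving out 1 library at a time, KO against WT gave 1 to 6 genes in saline BM, 1 to 504 in BM after G-CSF and 1 to 31 in spleen. G-CSF gave 967 to 1366 in WT and 865 to 1909 in KO, spleen against BM 674 to 1819 in WT and 97 to 198 in KO, and the interactions 0 to 7 (G-CSF) and 0 to 245 (tissue). The extremes belong to the libraries named beside each comparison, and to WT saline replicate 4 (1366), KO BM replicate 3 (1909 and 198) and WT BM replicate 2 (1819).

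Of 70 list calls by camera, 7 held with an estimated correlation, namely HSC identity and multipotent progenitor genes with G-CSF in both genotypes, the unfolded protein response with G-CSF in WT, and HSC identity and interferon genes in KO spleen. Fry called 43 of the 279 pairs of a list and a comparison, 29 of them among the 70. Without Cd53, a test also added after seeing the data, the tetraspanins in spleen no longer passed, which left 69. In saline BM, the medians of KO against WT ran from -0.203 to 0.01 for the G2/M targets and from -0.174 to 0.038 for G1/S genes, reversed without KO saline replicate 1, and from 0.002 to 0.167 for oxidative phosphorylation and -0.025 to 0.319 for mitochondrial genes, reversed in the test without KO saline replicate 3. Oxidative phosphorylation in KO spleen against BM ran from -0.124 to 0.002, reversed without KO spleen replicate 4, and its interaction with tissue was 0.024 with GC and length trends removed. Other list medians that moved over 1.5 times with 1 library left out included, in KO against WT in saline BM, those of interferon (-0.01 to 0.223), cholesterol (0.059 to 0.303), ribosome biogenesis (0.027 to 0.122) and DNA repair genes (-0.192 to -0.095), and, with G-CSF in WT BM, that of adhesion genes (0.075 to 0.18). In WT spleen against BM they included those of G1/S (-0.341 to -0.147), HSC identity (0.095 to 0.22) and mitochondrial genes (0.121 to 0.248), and in KO those of B cell (-0.484 to -0.139), unfolded protein (-0.147 to -0.042) and DNA repair genes (-0.207 to -0.08). In the interaction with tissue they included oxidative phosphorylation (-0.25 to -0.113) and unfolded protein genes (0.09 to 0.187). Megakaryocyte genes in the interaction with G-CSF (-0.268 to -0.114) and tetraspanins in KO against WT spleen (-0.137 to -0.048) moved as well. With genes above 4 CPM, which are fewer, the correlation across genes between saline BM and spleen was -0.104, and between the responses to G-CSF 0.727.

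Median-centring moved the median of all genes by 0.11 for spleen against BM in WT and by -0.12 for the interaction with tissue. The labels do not say what a shared replicate number means, so spleen and BM were compared as unpaired. Of 17 pairs with the same number, within and across genotypes, 6 had deviations correlated above 0.1 (range -0.23 to 0.26). In 8 of them the best match carried the same number. The consensus correlation of BM and spleen libraries with the same number was 0.037. These values do not settle whether such libraries came from the same mouse. With the number as a block, KO against WT in BM after G-CSF gave 31 genes. The edgeR and DESeq2 count tests named beforehand are not reported, although whole reads could be recovered and edgeR had been named for that case. Voom on those reads took their place.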

Other observations

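Transcripts of 2 of the 4 gate genes, Cd48 and Ly6a, rose with G-CSF in BM of both genotypes. Cd48, whose protein the sort excludes, rose by 1.78 ± 0.31 in WT and 1.79 ± 0.31 in KO on the log2 scale, to 3.85 and 4.04 log2 CPM. Ly6a rose by 1.16 ± 0.12 in WT and 0.55 ± 0.12 in KO, with an interaction of -0.62 ± 0.17 (adjusted p = 0.370); the KO call was lost without KO saline replicate 2 (adjusted p = 0.0538). In WT spleen against BM, Slamf1 was at 0.54 ± 0.18 (adjusted p = 0.0494), a call lost in each of the 7 omissions of 1 library (adjusted p = 0.0568 to 0.139), and Kit at -0.55 ± 0.20 (adjusted p = 0.0654, and 0.0387 without WT spleen replicate 3). Between genotypes in G-CSF-treated mice, Ly6a was at -0.30 ± 0.12 in BM and -0.22 ± 0.11 in spleen, and Kit at 0.09 ± 0.20 and 0.46 ± 0.18, none past the threshold.

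Lists of 9 kinds passed the camera test at the preset correlation in 0 of the 9 comparisons: BCL2 family, CDK inhibitors and cyclins, DREAM and MuvB subunits, TNF and NF-kB, glycolysis and hypoxia, mast cell and basophil, monocyte and macrophage, p53 target, and stromal and endothelial genes. The lowest adjusted p among them was 0.0557, for monocyte and macrophage genes. Per library, the mean of the DREAM and MuvB subunits was lower in 3 of 3 KO than in every WT library of saline BM. The group means differed by 0.10 (exact permutation p = 0.0571, the smallest possible, and adjusted p = 0.154 over 27 tests). The libraries nearly touched, with the highest KO library at 0.05 and the lowest WT library at 0.052. The most abundant member of the erythroid list was Car2, at 12.02 to 12.43 log2 CPM in the 6 groups, and that of the B cell list was Cd74, at 8.84 to 9.45; both were picked for their level after it was seen.

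Among 127 genes within 10 Mb of Cd53, 30.7% ± 4.1 (SE) had an unadjusted p under 0.05 in at least 1 of the 3 comparisons of KO with WT, against 25.5% of 13443 other genes. Transcripts of the Y-linked genes Ddx3y and Eif2s3y were read in each library, at no less than 6.93 and 6.19 log2 CPM, and Xist reached at most 1.67.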
